A study of Gallus gallus with 4 samples.

How the data were processed

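RNA from dissected dermal papilla complexes of growing dorsal feathers was extracted in Trizol and sequenced from Illumina TruSeq libraries, per the labels' protocols. The 4 libraries were 2 from the anterior and 2 from the posterior side of the papilla, and the library names carry the numbers 293 to 296 in that order. The deposited values are RPKM per gene, made by the authors, in a table of 15386 genes whose name gives Ensembl release 78. The submitters' processing notes name TopHat2, Partek and the chicken build galGal4, without versions or settings. How reads were counted is not given in the sources used here. Of the gene identifiers, 2745 were Ensembl IDs with no symbol, and 12641 were symbols or other names. Of those, 11154 were current symbols in an NCBI RefSeq gene table (assembly bGalGal1.mat.broiler.GRCg7b) and 779 matched only as a unique synonym. That assembly is not the authors' build, so it served for names only and no positions are given. The synonyms matched 35 list members.

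RPKM keeps no read totals. Ratios of values under 0.3 RPKM between libraries fell within 0.002 (natural log) of a ratio of whole numbers up to 5 for 51.1% to 55.4% of genes, against 0.8% to 1.23% by chance, and this gave the relative depth of the libraries. The remaining values were not whole steps, so read counts were not rebuilt and count tests were not used. Genes at 0 numbered 669, 639, 969 and 646 in anterior libraries 1 and 2 and posterior libraries 1 and 2. At most 1 gene had an identical value above 0 in any pair of libraries, so no library was a copy of another.

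Values were compared as log2(RPKM + 1), so a fold change understates that of low genes. The 10939 genes with at least 1 RPKM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no covariates and 2 residual degrees of freedom. Differences are anterior minus posterior. Genes at least 2-fold apart with non-overlapping libraries were counted as a description. Gene lists for signalling pathways, patterning, matrix, proliferation, other cell types and sample state, 33 in all, were fixed before the data were examined. Camera tested the 31 lists with at least 5 tested members. The W-linked list and the skeletal muscle list had too few members. The rule for named genes took, per direction, up to 12 genes past the threshold. Since none passed, it took the genes of smallest unadjusted p with a symbol, at least a 2-fold difference, non-overlapping libraries and a mean of at least 5 RPKM on the higher side. It also took up to 4 members of smallest p per described list and the feather axis genes. Other genes are named to show the spread within a list or library, and were chosen after their values were seen.

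Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 RPKM, median ratio scaling, quantile normalization, eBayes without trend or with the robust option, an estimated correlation in camera, and leaving out each library. A block for the library number and a smooth muscle score as a covariate were added after the data were seen. Leaving out a library leaves a single library on its side, which is then assumed to vary like the other side.

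The test was run on simulated data with the real genes' means and 200 changed genes, in 10 simulations over 10939 genes. With each gene's spread as fitted over all 4 libraries, 5.4% of 2-fold, 88.2% of 4-fold and 99.2% of 8-fold changes were recovered. With the spread of the anterior libraries alone, 71% of 2-fold and 99.7% of 4-fold changes were recovered. False calls averaged 11.8 of 140.2 and 18.8 of 201.5 calls. Camera found a list of shifted genes in 10 of 10 simulations and called 0 lists of unshifted genes. Simulated genes vary independently, unlike genes in tissue. Their spreads were the fitted ones, which eBayes had already drawn together, so they vary less between genes than the real spreads. The recovered shares are therefore likely too high for the real data. There, ENSGALG00000019852 had a log2 difference of 2.50 with a standard error of 0.25, and a limma adjusted p of 0.964. Python 3.11.15 and matplotlib 3.10.9 were used for the depth estimate and the plots.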

Results

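RNA was measured in the dermal papilla complex of growing dorsal feathers of White Leghorn chickens. The dermal papilla is the cluster of mesenchymal cells at the base of the feather follicle that signals to the epithelium around it. Tissue from the anterior side and tissue from the posterior side of the papilla were sequenced, with 2 libraries from each side and 4 in all. The labels do not say that the libraries came from separate birds. The p-values of single genes below therefore measure only the spread between these samples, which may be technical. Camera p-values at the preset correlation compare the genes of a list with other genes, treated as nearly independent. They do not measure the spread between samples. Expression was given as RPKM for 15386 genes. The median over genes was 4.89 and 4.68 RPKM in anterior libraries 1 and 2, and 3.75 and 4.62 RPKM in posterior libraries 1 and 2. The number of reads behind these values is unknown. Relative to anterior library 1, the depth read from the steps between low values was 99.9% in anterior library 2, 77.0% in posterior library 1 and 99.6% in posterior library 2.

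The design asked which genes differ between the anterior and the posterior side of the papilla. Among the genes chosen by a fixed rule, a pigment gene and a steroid gene stood at the top of the anterior side. ASIP, which encodes the agouti signalling protein that blocks the melanocortin 1 receptor, averaged 8.56 ± 1.42 RPKM (SD, n = 2) in anterior and 2.35 ± 0.493 RPKM (n = 2) in posterior tissue, a log2 difference of 1.51 with a standard error of 0.27. SRD5A2, a steroid reductase that makes dihydrotestosterone, measured 186 and 48.0 RPKM in the anterior and 16.4 and 13.1 RPKM in the posterior libraries. The melanosome protein gene PMEL measured 8.56 and 11.03 RPKM in the anterior against 0.577 and 3.47 RPKM in the posterior libraries. DRAXIN, a secreted guidance protein that antagonises WNT signalling, averaged 21.7 ± 5.13 RPKM in anterior and 5.86 ± 4.88 RPKM in posterior tissue. The catenin gene CTNNA2 averaged 23.9 RPKM in anterior tissue against 3.12 and 11.5 RPKM in posterior libraries 1 and 2, and the adhesion gene CADM1 7.05 RPKM against 1.85 and 3.90 RPKM. Genes of the matrix and its assembly on the anterior side were THBS2, at a mean of 134 RPKM against 40.3 and 85.2 RPKM, the collagen crosslinking enzyme LOX, at 21.3 RPKM against 6.71 and 13.8 RPKM, and COL23A1, at 6.49 RPKM against 0.840 and 3.41 RPKM. The rule also took FNDC1 with a log2 difference of 1.52, AQP5, a water channel, with 1.23 and SCUBE3 with 1.23. Leaving out posterior library 1 made the log2 difference smaller for 10 of the 12 anterior genes, all but ASIP and SRD5A2. It fell to 1.12 for DRAXIN, 0.96 for CTNNA2, 0.75 for COL23A1, 0.63 for SCUBE3 and 0.59 for LOX, the smallest of the 12. On the scale of the rule, log2(RPKM + 1), at least a 2-fold difference was left for 5 of the 12 (ASIP, SRD5A2, PMEL, DRAXIN and FNDC1), and in RPKM for 7, with CTNNA2 and AQP5 added.

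On the posterior side, RASD2, a small GTPase, averaged 85.8 ± 15.4 RPKM against 37.3 ± 5.16 RPKM in anterior tissue (n = 2 each), a log2 difference of -1.18 with a standard error of 0.27. The dopamine receptor gene listed as D1A averaged 5.24 RPKM against 1.95 RPKM, TM4SF1 averaged 13.2 RPKM against 4.97 RPKM, and LRRC32, which tethers latent TGF-beta to the cell surface, measured 25.0 and 13.7 RPKM in posterior libraries 1 and 2 against a mean of 8.18 RPKM. STC2, a secreted glycoprotein, averaged 8.16 RPKM in posterior tissue against 6.06 and 1.57 RPKM in anterior libraries 1 and 2, and COPN5L2 averaged 22.3 RPKM against 11.2 and 3.79 RPKM, so their size depends on which anterior library is compared. The other 6 genes had most of their posterior mean from posterior library 1. PRUNE2 measured 38.6 RPKM there and 7.84 RPKM in posterior library 2, PGM5 85.1 and 17.5 RPKM, TRPV2 67.2 and 16.8 RPKM, and FBXO32 45.5 and 13.5 RPKM. ASB2 measured 8.28 and 2.13 RPKM, and the serotonin receptor gene HTR2B 14.5 and 1.73 RPKM. The unadjusted limma p of these 6 genes ran from 0.0643 (ASB2) to 0.123 (HTR2B), and it was 0.0735 for STC2. For the 12 anterior genes it ran from 0.00197 (ASIP) to 0.0326 (SCUBE3). With posterior library 1 left out, 4 of the 12 posterior genes (D1A, TM4SF1, COPN5L2 and STC2) kept at least a 2-fold difference on the scale of the rule, and 5 in RPKM, with RASD2 added. Smooth muscle genes were also high in posterior library 1, with DES at 1158 RPKM there and 3.62 RPKM in posterior library 2.

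**Figure D1:**
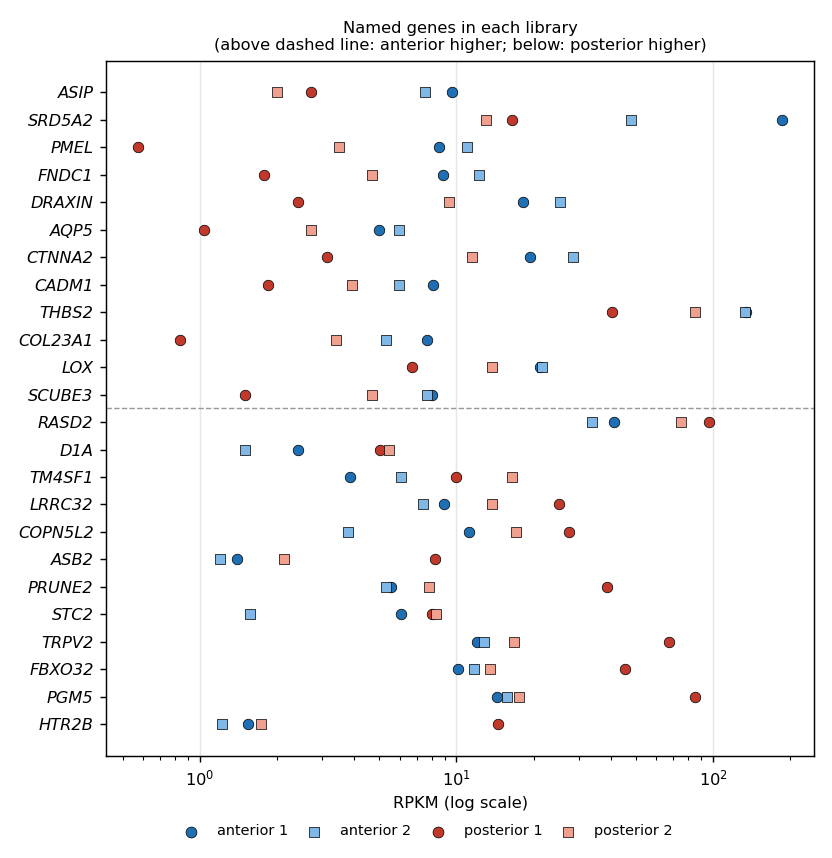
RPKM (log scale) of the 24 genes named by the fixed rule in each of the 4 libraries, with 12 genes higher in anterior tissue above the dashed line and 12 higher in posterior tissue below it. Each point is a library. ASIP lies between 7.56 and 9.57 RPKM in anterior and between 2.00 and 2.70 RPKM in posterior libraries, while PGM5 lies at 85.1 RPKM in posterior library 1 and between 14.3 and 17.5 RPKM elsewhere.

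None of the named genes passed the test. Of 10939 genes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.964. At an unadjusted p under 0.05 there were 103 genes, 78 higher in anterior and 25 higher in posterior tissue, where 547 would arise with no difference and no structure within the sides. The low count does not show that the sides are alike. The column names number the libraries 1 and 2 within each side. Of 198 genes at least 2-fold apart between these numbers within both sides, 187 differed in the same direction. Such differences enter the error of this fit. The largest effects relative to their error belonged to a pair of unnamed Ensembl genes. ENSGALG00000019852 measured 11.5 and 12.2 RPKM in anterior and 1.16 and 1.38 RPKM in posterior libraries, a log2 difference of 2.50 with a standard error of 0.25. ENSGALG00000027770 measured 49.2 and 38.7 RPKM against 7.70 and 4.95 RPKM, a difference of 2.63 with a standard error of 0.30. These counts depend on the model. With a block for the library number, added after the data were seen, 617 genes had an unadjusted limma p under 0.05. Both Ensembl genes then passed (adjusted p = 0.0147 and 0.012). That fit leaves 1 residual degree of freedom, and no label ties the numbers of the sides to each other. Without posterior library 2, which leaves posterior library 1 alone on its side, 226 genes passed, 138 higher in anterior and 88 in posterior tissue. With 2 libraries against 2, an exact permutation test cannot give a two-sided p below 0.333.

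By size alone, 70 genes were at least 2-fold higher in anterior tissue with both anterior libraries above both posterior libraries, and 21 genes were at least 2-fold higher in posterior tissue in the same way. Non-overlapping groups occurred in 26.2% of tested genes, where chance gives 33.3%. The excess of anterior genes depended on scaling: the counts were 46 and 34 after median ratio scaling, and 43 and 39 after quantile normalization. The median log2 difference over all tested genes was 0.11 as deposited and -0.0044 after median ratio scaling, so list medians below are also given relative to all genes. Each library moved these counts. They were 214 and 134 without anterior library 1, 143 and 59 without anterior library 2, 64 and 42 without posterior library 1, and 1003 and 388 without posterior library 2. Smaller pseudocounts added genes, with 168 and 42 at 0.1 and 110 and 28 at 0.5.

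Genes with known roles along the feather axes were listed in advance, and 26 of the 31 found in the file were tested. None passed, and none passed when adjusted over the list alone. MMP2, a matrix metalloproteinase, separated the sides with the least spread, at 142 and 137 RPKM in anterior and 248 and 242 RPKM in posterior libraries, a log2 difference of -0.80 with a standard error of 0.23. The WNT antagonist FRZB measured 86.2 and 71.7 RPKM in anterior and 114 and 122 RPKM in posterior libraries, and another, DKK2, 6.11 and 6.06 RPKM against 4.17 and 4.45 RPKM. SHH, WNT6 and WNT5A had their lowest values in posterior library 1. SHH measured 2.24 RPKM there and 17.5 to 23.3 RPKM in the other libraries, WNT6 2.08 RPKM against 13.7 to 22.8 RPKM, and WNT5A 17.6 RPKM against 66.5 to 75.6 RPKM. The retinoic acid binding protein gene CRABP1, listed as CRABP-I, measured 4.19 RPKM there and 19.6 to 36.5 RPKM elsewhere, and the activin antagonist FST 43.3 RPKM against 97.0 to 112 RPKM. Some genes differed in opposite directions depending on which posterior library is compared with the anterior mean. BMP4 averaged 21.7 RPKM in anterior tissue and measured 19.19 and 30.04 RPKM in posterior libraries 1 and 2, BMP2 5.37 RPKM against 3.51 and 10.3 RPKM, the BMP antagonist GREM1 5.32 RPKM against 2.32 and 10.1 RPKM, and WNT3A 2.15 RPKM against 1.02 and 2.28 RPKM. GDF10, NOG, SPRY4, SOX2 and TBX5 stayed below the expression filter.

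Among 31 gene lists fixed before the data were examined, 8 passed limma's camera test with a preset correlation between genes of 0.01, which compares the list with all other genes. None of the 8 passed with an estimated correlation, where the adjusted p = 0.81 for each. Camera then judges a list on the 2 residual degrees of freedom of the fit, so hardly any list could pass. This failure therefore does not decide whether the 8 lists differ. With posterior library 1 left out, no list passed with an estimated correlation either (smallest adjusted p = 0.946), so the calls given below without that library hold for the preset correlation only. No list held a gene that passed over all genes, and none held a gene that passed when adjusted over the list alone.

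The list that differed most was smooth muscle and pericyte markers, higher in posterior tissue (adjusted p = 4.37e-06) with a median log2 difference of -1.33 over 16 tested members, or -1.44 relative to all genes. That difference came from posterior library 1. The muscle myosin gene MYH11 measured 1222 RPKM in this library and 16.8 to 50.5 RPKM in the others, and the intermediate filament gene DES 1158 RPKM against 3.62 to 32.4 RPKM. TAGLN, an actin-binding protein gene of smooth muscle, measured 821 RPKM against 20.1 to 61.9 RPKM, and MYLK, the myosin light chain kinase gene, 354 RPKM against 21.7 to 29.1 RPKM. The actin gene ACTG2 differed less, at 173.9 RPKM in posterior library 1 against 101.5 to 148.5 RPKM. Among the list's pericyte genes, RGS5 measured 48.1 RPKM in posterior library 1 and 34.5 to 43.0 RPKM in the others, and PDGFRB 5.07 RPKM against 9.83 to 14.5 RPKM. The list's median without that library was 0.19, in the opposite direction (adjusted p = 0.0219 with the preset correlation).

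**Figure D2:**
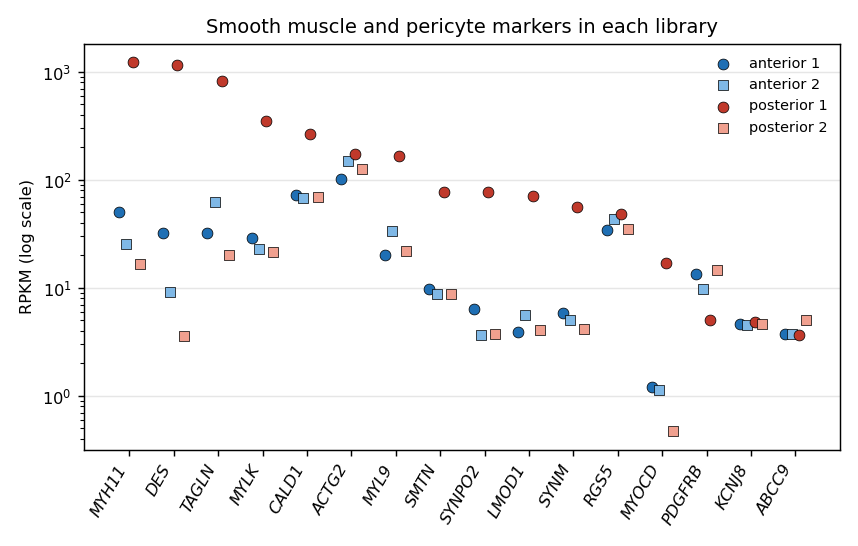
RPKM (log scale) of the 16 tested smooth muscle and pericyte markers, with each point a library. MYH11, DES and TAGLN lie between 821 and 1222 RPKM in posterior library 1 and at or below 61.9 RPKM in the other 3 libraries, while KCNJ8 lies between 4.57 and 4.84 RPKM in all 4.

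Genes of the Notch pathway were higher in anterior tissue as a list (adjusted p = 0.000105), with a median log2 difference of 0.52, or 0.41 relative to all genes. All 14 tested members had positive differences, and 9 had both anterior above both posterior libraries. HEYL, a transcription factor induced by Notch, measured 3.99 and 3.37 RPKM in anterior and 1.25 and 2.31 RPKM in posterior libraries. NRARP measured 4.15 and 3.37 RPKM against 1.80 and 2.43 RPKM, HEY1 15.7 and 17.8 RPKM against 6.32 and 13.3 RPKM, and DLK2 3.82 and 2.89 RPKM against 0.906 and 2.25 RPKM. The list still passed with the preset correlation when posterior library 1 was left out (adjusted p = 0.0234), with a median of 0.26.

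Cell proliferation genes were higher in anterior tissue as a list (adjusted p = 4.27e-05), with a median log2 difference of 0.43, or 0.32 relative to all genes, and with positive differences in 39 of 43 members. MCM3, part of the replicative helicase, measured 23.4 and 25.3 RPKM in anterior and 4.41 and 21.2 RPKM in posterior libraries. TOP2A measured 37.2 and 30.5 RPKM against 9.85 and 29.4 RPKM, and the mitotic kinase gene PLK1 27.0 and 27.1 RPKM against 7.69 and 24.5 RPKM. The list was not uniform, with an SD of 0.32 over members. MKI67 differed less, at 28.98 and 24.32 RPKM against 21.01 and 23.65 RPKM, and NUSAP1 measured 27.64 and 25.4 RPKM against 28.21 and 25.58 RPKM. When posterior library 1 was left out, the median was 0.095 and the list did not pass (adjusted p = 0.0877).

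The lists of WNT ligands and R-spondins (adjusted p = 0.0241) and of WNT target genes and transducers (adjusted p = 0.0166) were higher in anterior tissue. Their median log2 differences were 0.44 over 15 members and 0.30 over 23 members, or 0.32 and 0.19 relative to all genes. WNT2B measured 3.01 and 2.36 RPKM in anterior and 0.0584 and 0.632 RPKM in posterior libraries, and WNT11 56.1 and 28.2 RPKM against 24.6 and 24.3 RPKM. LEF1, a transcription factor of the WNT pathway listed as LEF-1, measured 40.5 and 47.9 RPKM against 10.8 and 36.2 RPKM, and the receptor gene LGR6 4.76 and 3.16 RPKM against 2.25 and 1.13 RPKM. Leaving out posterior library 1 gave medians of 0.0035 (adjusted p = 0.99) and 0.12 (adjusted p = 0.292). The ligands also did not pass with no filter (adjusted p = 0.0709), and at a filter of 5 RPKM neither the ligands (adjusted p = 0.369) nor the targets (adjusted p = 0.0521) passed.

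Melanocyte markers were higher in anterior tissue as a list (adjusted p = 0.0102), with a median log2 difference of 0.41 over 10 tested members, or 0.30 relative to all genes. Beside PMEL, TYRP1, an enzyme of pigment synthesis, measured 3.57 and 5.55 RPKM in anterior and 0.616 and 1.75 RPKM in posterior libraries, and MLANA 2.29 and 3.46 RPKM against 0.560 and 1.25 RPKM. MITF, listed as CMI9, measured 15.9 and 18.1 RPKM against 13.7 and 19.6 RPKM. Tyrosinase, TYR, was at or below 0.581 RPKM in every library and was not tested. Without posterior library 1 the list's median was 0.11 and it passed with the preset (adjusted p = 0.0234) but not with an estimated correlation (adjusted p = 0.946), and without posterior library 2 its median was 0.73 and it did not pass (adjusted p = 0.0962).

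Leukocyte markers (adjusted p = 0.00379) and ribosomal protein genes (adjusted p = 0.00188) were higher in posterior tissue as lists, by small amounts. The median log2 difference was -0.093 over 33 leukocyte markers and -0.074 over 73 genes of the ribosomal list, or -0.21 and -0.19 relative to all genes. The members of the ribosomal list with the smallest p were the kinase genes RPS6KB2, RPS6KA5 and RPS6KA2, which the symbol rule takes in although they encode signalling kinases and not ribosomal proteins. Without posterior library 1 the medians were 0.072 (adjusted p = 0.806) and 0.0074 (adjusted p = 0.974), and neither list passed. The ribosomal list also did not pass without anterior library 1 (adjusted p = 0.295), and its median was 0.0045 after quantile normalization (adjusted p = 0.881).

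**Figure D3:**
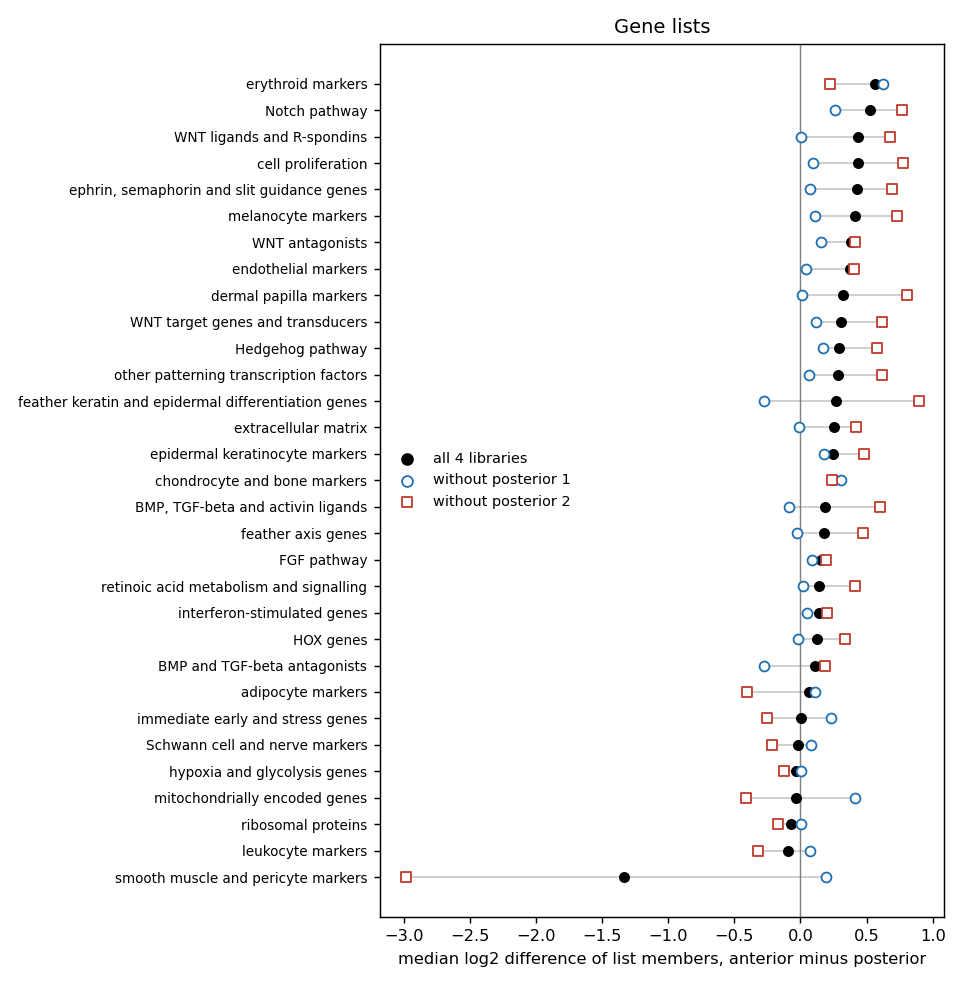
Median log2 difference (anterior minus posterior) over the members of each of the 31 gene lists, with all 4 libraries (filled points), without posterior library 1 (open circles) and without posterior library 2 (open squares). The smooth muscle list moves from -1.33 to 0.19 when posterior library 1 is left out, and the Notch list from 0.52 to 0.26.

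The other signalling and patterning lists did not pass. Hedgehog pathway genes had a median log2 difference of 0.29 (adjusted p = 0.0924), with the target GLI1 at 7.84 and 6.62 RPKM in anterior against 1.66 and 4.98 RPKM in posterior libraries. Ephrin, semaphorin and slit guidance genes had a median of 0.43 (adjusted p = 0.0619). Both lists passed after median ratio scaling, with adjusted p = 0.0459 and 0.0201. Dermal papilla markers had a median of 0.32 over 22 members (adjusted p = 0.321). Among them CORIN, a protease gene of the papilla, measured 6.86 and 2.13 RPKM in anterior and 0.308 and 0.562 RPKM in posterior libraries, and alkaline phosphatase, ALPL, 37.2 and 33.7 RPKM against 3.46 and 19.3 RPKM. The median was 0.38 for WNT antagonists (adjusted p = 0.703), 0.18 for BMP, TGF-beta and activin ligands (adjusted p = 0.521) and 0.11 for their antagonists (adjusted p = 0.566). It was 0.14 for retinoic acid genes (adjusted p = 0.639), 0.16 for the FGF pathway (adjusted p = 0.789) and 0.13 for HOX genes (adjusted p = 0.521). Other patterning transcription factors had a median of 0.28 (adjusted p = 0.236), with FOXD1 at 12.4 and 18.5 RPKM against 5.81 and 9.05 RPKM. Extracellular matrix genes had a median of 0.26 over 47 members (adjusted p = 0.557), and COL14A1 measured 5.03 and 4.74 RPKM against 2.02 and 1.94 RPKM. The feather axis list had a median of 0.18 (adjusted p = 0.931). When posterior library 1 was left out, the median turned to -0.084 for BMP, TGF-beta and activin ligands, -0.27 for their antagonists, -0.021 for HOX, -0.011 for matrix and -0.029 for feather axis genes. The antagonists then passed as higher in posterior tissue with the preset correlation (adjusted p = 0.00689), and Hedgehog genes passed as higher in anterior tissue (adjusted p = 0.0477) with a median of 0.17. The medians without that library were 0.16 for WNT antagonists, 0.085 for the FGF pathway, 0.075 for guidance, 0.066 for other patterning, 0.016 for retinoic acid and 0.014 for dermal papilla genes. With all 4 libraries, median and test differed in sign for the feather axis list and for the BMP and TGF-beta antagonists, where camera pointed to posterior tissue.

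The libraries did not group by side. Posterior library 2 was closest to anterior library 2, with a Pearson correlation of 0.987 across tested genes, and 121 genes differed by over 2-fold between them. The anterior libraries correlated at 0.964 and the posterior libraries at 0.901, with 344 and 1549 genes over 2-fold apart. These are correlations across genes, which are not independent replicates. The first principal component held 76.8% of the variance and placed posterior library 1 at 56.9, with the other libraries between -28.0 and -5.48. The next component, with 16.7%, placed anterior library 1 at 27.2 and the others between -11.0 and -6.71. Mitochondrial transcripts made up 31.3% of the RPKM total in posterior library 1 and 24.3%, 27.1% and 20.7% in anterior library 1, anterior library 2 and posterior library 2.

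**Figure D4:**
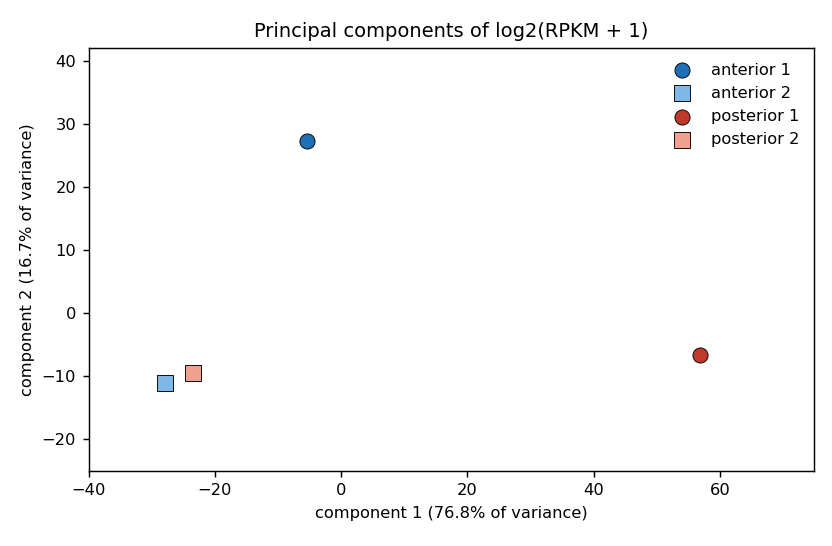
Positions of the 4 libraries on the first principal components of log2(RPKM + 1) over 10939 genes, in component units, with each point a library. Posterior library 1 lies at 56.9 on component 1, and anterior library 2 and posterior library 2 lie close together at -28.0 and -23.5.

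W-linked genes, which female chickens carry, were compared as a check on sex. HINTW was listed at 0 in 3 libraries and at 0.0294 RPKM in anterior library 2, and SPINW was at or below 0.0107 RPKM in all 4. ATP5A1W measured 6.76 and 4.19 RPKM in anterior and 4.25 and 5.08 RPKM in posterior libraries. The sides overlapped for ATP5A1W, and chromosome Z was not analysed here. ATP5A1W was measured in every library while HINTW and SPINW were near absent, so these genes do not settle the sex of the birds or whether it was balanced.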

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

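The replicate block and the smooth muscle covariate were chosen after the data were seen, and the other alternatives before. The count of genes past the threshold was 0 under each other setting with all 4 libraries and ranged from 0 to 226 with a library left out (0 to 138 higher in anterior, 0 to 88 in posterior), above 0 only without posterior library 2. The 2-fold counts ranged with a library left out from 64 to 1003 for anterior and from 42 to 388 for posterior tissue. They were 168 and 42 with a pseudocount of 0.1, 110 and 28 with 0.5, 46 and 34 after median ratio scaling, and 43 and 39 after quantile normalization. Of the 91 genes counted, 91 were kept with either pseudocount, 67 after median ratio scaling and 64 after quantile normalization. Without anterior library 1, anterior library 2, posterior library 1 and posterior library 2 in turn, 72, 75, 23 and 87 were kept. All 24 named symbols and both named Ensembl genes kept their sign wherever they were tested, which their non-overlapping libraries make certain when a library is left out. The mean correlation of posterior library 1 with the others was 0.907, 0.947 with no filter, where more low genes enter, and 0.884 at a filter of 5 RPKM. Lists past the threshold numbered 8 to 15 with a library left out and 0 with an estimated correlation. With an estimated correlation hardly any list could pass, given the few residual degrees of freedom. That setting leaves the median log2 differences as they were, at -1.33 (smooth muscle), 0.43 (proliferation), 0.52 (Notch), -0.074 (ribosomal), -0.093 (leukocyte), 0.41 (melanocyte), 0.30 (WNT targets) and 0.44 (WNT ligands). With each library left out in turn, the medians of the lists that passed with all libraries ranged from -2.99 to 0.19 for smooth muscle, -0.32 to 0.072 for leukocyte, -0.17 to 0.0074 for ribosomal, 0.095 to 0.78 for proliferation, 0.11 to 0.73 for melanocyte, 0.26 to 0.77 for Notch, 0.0035 to 0.68 for WNT ligand and 0.12 to 0.62 for WNT target genes. Among lists that did not pass with all libraries, the range was -0.41 to 0.41 for mitochondrial, -0.25 to 0.27 for immediate early, -0.41 to 0.11 for adipocyte, -0.27 to 0.18 for BMP antagonist and 0.014 to 0.81 for dermal papilla genes. It was 0.042 to 0.41 for endothelial, 0.075 to 0.69 for guidance, -0.027 to 0.56 for keratinocyte, -0.046 to 0.97 for erythroid, -0.011 to 0.42 for matrix and -0.50 to 0.89 for feather keratin genes. It was 0.17 to 0.57 for Hedgehog, -0.021 to 0.34 for HOX, 0.066 to 0.61 for other patterning, -0.084 to 0.60 for BMP, TGF-beta and activin ligand and -0.029 to 0.48 for feather axis genes. It was 0.16 to 0.41 for WNT antagonist, 0.016 to 0.41 for retinoic acid, 0.085 to 0.19 for FGF, -0.17 to 0.11 for hypoxia, -0.21 to 0.076 for nerve, 0.045 to 0.28 for interferon-stimulated and 0.24 to 0.33 for chondrocyte and bone genes. At a filter of 5 RPKM, guidance (0.49) and Hedgehog genes (0.62) passed, and WNT ligands (0.60) and targets (0.29) did not. WNT ligands did not pass with no filter (0.28). After median ratio scaling erythroid (0.44), Hedgehog (0.18) and guidance genes (0.30) passed. After quantile normalization keratinocyte (0.18) and erythroid genes (0.44) passed and ribosomal genes turned (0.0045). With the smooth muscle covariate, BMP antagonists (-0.23), Hedgehog (0.25) and erythroid genes (0.68) passed and mitochondrial genes turned and passed (0.30), while smooth muscle (-0.11), ribosomal (0.00022), leukocyte (0.0018), WNT ligand (0.068) and WNT target genes (0.15) did not pass. The cause was not tested for any of these. Without posterior library 1, the Notch and melanocyte calls were kept, smooth muscle genes passed in the opposite direction, and the proliferation, leukocyte, ribosomal and both WNT lists did not pass, with leukocyte and ribosomal medians of the opposite sign. Erythroid, Hedgehog, mitochondrial and immediate early genes then passed as higher in anterior tissue, and BMP antagonists as higher in posterior tissue. With the covariate 3 of the 8 calls were kept and 5 lost. The labels give the sides no shared replicate numbers, but the column names number the libraries 1 and 2 within each side, and differences between numbers 1 and 2 within the sides correlated across genes at 0.488. With the replicate block, which leaves 1 residual degree of freedom, 2 genes passed, both higher in anterior tissue, ENSGALG00000027770 (adjusted p = 0.012) and ENSGALG00000019852 (adjusted p = 0.0147). The block gave 11 lists, adding guidance (0.43), erythroid (0.56) and Hedgehog genes (0.29). With the covariate 0 genes and 7 lists passed. Depth limits low genes most in posterior library 1, at 77.0% of the depth of anterior library 1.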

Other observations

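The remaining lists, of other cell types and of sample state, did not pass the camera test with all 4 libraries. Globin transcripts were highest in anterior library 2, where HBAA measured 548 RPKM against 129, 227 and 136 RPKM in anterior library 1, posterior library 1 and posterior library 2. The erythroid list had a median log2 difference of 0.56 (limma camera, adjusted p = 0.0845) and passed after median ratio scaling (adjusted p = 0.0459) and quantile normalization (adjusted p = 0.0489). Its median changed sign within the range given above for leaving out each library in turn. CA2, a carbonic anhydrase gene on the erythroid list, measured 44.3 and 57.1 RPKM in anterior and 25.4 and 32.3 RPKM in posterior libraries, and the transferrin receptor gene TFRC 13.7 and 11.1 RPKM against 3.53 and 8.06 RPKM. Epidermal keratinocyte markers had a median of 0.24 (adjusted p = 0.236, and 0.0366 after quantile normalization). KRT5 measured 796 RPKM in anterior library 1 and 182 to 266 RPKM in the others. Interferon-stimulated genes had a median of 0.14 (adjusted p = 0.35), which turned to -0.022 after quantile normalization, with the antigen presentation genes BF1 at 125 and 112 RPKM in anterior against 71.3 and 77.97 RPKM in posterior libraries and TAP2 at 10.2 and 12.9 RPKM against 3.97 and 8.29 RPKM.

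Nerve markers had a median of -0.018 (adjusted p = 0.0619), with the neurofilament gene NEFL at 2.60 and 3.18 RPKM in anterior and 4.68 and 5.72 RPKM in posterior libraries. Hypoxia and glycolysis genes had a median of -0.032 (adjusted p = 0.112), and LDHA, lactate dehydrogenase, measured 703 and 749 RPKM against 1090 and 967 RPKM. Endothelial markers had a median of 0.37 (adjusted p = 0.362), chondrocyte and bone markers 0.24 (adjusted p = 0.703) and adipocyte markers 0.066 (adjusted p = 0.359). Feather keratin and epidermal differentiation genes had a median of 0.27 (adjusted p = 0.362), immediate early and stress genes 0.0051 (adjusted p = 0.415) and mitochondrially encoded genes -0.033 (adjusted p = 0.357). Camera pointed to posterior tissue for the adipocyte, keratin and stress lists, against the sign of their medians, and scaling by median ratio turned the adipocyte median to -0.070 and the stress median to -0.13. Without posterior library 1 the medians were 0.41 for mitochondrial and 0.23 for stress genes. Without posterior library 2 they were -0.41 and -0.25, so their direction depended on the library.

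In the paragraphs that follow, the tests of the smooth muscle list in single libraries, of the pooled proliferation and WNT lists, of dilution, of the keratinocyte list, of the splits of the libraries, and of the Notch list without posterior library 1 at an estimated correlation were chosen after the results were seen. The real split and the Notch list without that library at the preset correlation were chosen before. Posterior library 1 stood apart in both directions. In it 72 genes of at least 5 RPKM were over 4-fold above the highest other library. Another 57 genes were over 4-fold below the lowest other library, itself at least 5 RPKM. ODC1 measured 36.55 RPKM there against 312.4 to 478.4 RPKM, and EX-FABP 244 RPKM against 7.67 to 53.9 RPKM, both picked after their values were seen. The smooth muscle list had a median log2 of 3.09 above the other libraries. Scaling by a few abundant genes would move every gene by one factor, and after median ratio scaling the list's median was still 3.32 above the other libraries (standard error 0.72), which argues against it. A posterior trait shared by both posterior libraries would also raise the list in posterior library 2. The list's median there was -0.19 (standard error 0.10) relative to the anterior mean, which argues against such a trait in these libraries only. The standard errors in this paragraph and the next come from resampling list members 2000 times. They do not measure the spread between samples. Smooth muscle tissue in that dissection is a candidate explanation for the high smooth muscle genes. Whether it accounts for the genes that were low in that library was not tested. Of the 16 tested markers, 10 were over 4-fold above the highest other library, among them MYH11, DES and TAGLN. The actin gene ACTG2 was not, at 173.9 RPKM against 101.5 to 148.5 RPKM. ACTA1 on the skeletal muscle list measured 567 RPKM against 9.13 to 28.7 RPKM. TNNC1, the only other tested gene of that list, measured 3.36 RPKM against 3.05 to 4.25 RPKM. The pericyte genes RGS5, KCNJ8 and ABCC9 measured 48.1, 4.83 and 3.66 RPKM in posterior library 1, near their levels in the other libraries. PDGFRB, which the dermal papilla list also holds, measured 5.07 RPKM. All 16 markers reached 1 RPKM in at least 1 other library.

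The proliferation and WNT lists were higher in anterior tissue mainly through the same library. Over their 81 members the median log2 difference was 0.43 with all libraries and 0.093 without posterior library 1, so this library may account for most of it. For the Notch list the median without that library was 0.26, with an adjusted p of 0.0234 at the preset and 0.946 at an estimated correlation in limma's camera, so that posterior library 1 alone and a difference between the sides cannot be told apart with a single posterior library left. Even dilution by RNA of other tissue would lower all other markers alike. Leukocyte markers lay 0.95 above these 4 lists in posterior library 1 (standard error 0.18). This gap cannot decide on dilution, because the 4 lists and the leukocyte list had been called in opposite directions in the same data. Bias by GC content was not analysed here, and the position on the papilla stays open as an untested explanation.

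Libraries numbered 1 shared low feather keratins, in genes chosen after their values were seen. The keratin gene BKJ measured 21.6 and 12.4 RPKM in anterior and posterior library 1 against 362 and 330 RPKM in anterior and posterior library 2, while FOS measured 26.4 and 32.5 RPKM against 3.41 and 2.42 RPKM and KRT75 447 and 423 RPKM against 114 and 89.3 RPKM. Splitting the libraries by number gave 3 genes past limma's threshold and 1091 at an unadjusted p under 0.05, against 0 and 103 for the real split and 0 and 82 for the remaining one, which points to a structure of the samples that follows the number. The 3 genes were ENSGALG00000026512, ENSGALG00000028062 and ENSGALG00000028120, all lower in the libraries numbered 1, the last at 0.851 and 0.638 RPKM in anterior and posterior library 1 against 217.5 and 212.6 RPKM in anterior and posterior library 2 (adjusted p = 0.00443). What made this structure stays open. A bird, day or dissection shared by libraries of one number cannot be told apart from other sources of it, because no label ties the numbers of the sides to each other and 3 splits are too few to weigh this by counting. More epidermal keratinocytes in libraries numbered 1 also stay open: the keratinocyte list relative to all genes was 0.63 higher in anterior library 1 than in anterior library 2 but -0.032 in the posterior comparison, with an SD over members of 0.86.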
